A study of Saccharomyces cerevisiae BY4741 with 9 samples.

How the data were processed

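Gene expression was measured by RNA sequencing in budding yeast of the BY4741 background, in wild type (WT) and in a strain carrying scc2-4, a mutant allele of SCC2, the gene for the subunit of the cohesin loader that acts with Scc4. Per the labels' protocols, cells were grown to exponential phase at an optical density of 0.7 in rich medium with a complete amino acid supplement, RNA was extracted with acidic phenol and chloroform, and libraries were made with an Illumina TruSeq kit. The labels list 9 libraries: 3 WT and 3 scc2-4 libraries made after depletion of ribosomal RNA, and 3 WT libraries made from total RNA without depletion. The deposited table analysed here has 6 columns, 3 for WT and 3 for scc2-4, whose names give the genotype and a replicate number. The WT names do not give the preparation. They were taken as the ribo-depleted libraries, because the design text compares scc2-4 with WT and scc2-4 was prepared only by ribo-depletion. That assignment is an assumption, and it applies to every comparison reported. The 3 libraries not held by the table were not analysed here, so the planned comparison of ribo-depleted with total RNA libraries of WT, and the planned fit over all 9 libraries, were not run.

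Per the submitters' processing notes, reads were aligned with Bowtie to the sacCer3 genome; the version of the aligner and the counting tool are not given in the sources used here. The values deposited by the authors are RPKM, reads per kilobase of feature and per 1000000 reads, for 7130 features. Multiplying each RPKM value by the feature's span gave a sum of 1000000 per column, so the unit is relative to reads assigned to the table's features, not to all mapped reads. The span runs from start to end of the feature and includes introns. Low values were whole multiples of the value of 1 read. Of the values worth up to 100 reads in a column, 99.9% to 100% lay within 0.1 of a whole read. This gave the number of reads assigned to features in each library: 14730000, 17480000 and 17670000 in WT replicates 1, 2 and 3, and 18310000, 21930000 and 14930000 in scc2-4 replicates 1, 2 and 3. Of the 14 features of the repeated ribosomal DNA, 9 were at 0 in all libraries, as were 54 of the 299 transfer RNA genes, and 184 features in all were at 0 throughout. Reads that match several places in the genome were therefore evidently mostly left out, and values of genes with a near-identical copy are uncertain. No use of strand in the counting is stated, and 1416 features overlap another, so values of overlapping and antisense genes cannot be told apart. Gene names and positions came from the table. Of its 7130 identifiers, 6048 were found in the reference annotation of the same build, and 99.8% of these had the same start and end.

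Values were transformed to log2(RPKM + 1), each library was centred on its median feature, and features with a mean RPKM of at least 1 over the 6 libraries were kept, which left 6559. On this scale a fold change understates the change of features with low values. The median log2 shift between genotypes before centring was 0.037. Genotypes were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with a trend), with the Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Adjusted p-values for genes in all parts of the text come from this test unless another is named. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read the table and draw figures. On data simulated for these 6 libraries, with a replicate SD of 0.167 on the log2 scale and 200 features changed, the test recovered 70.1% of 67 features changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold among 6554 features tested, and 7.22% of its calls were false. The simulated noise was independent between features, with the same SD for each. No simulated library stood apart as WT replicate 1 did, so these rates need not hold for the measured libraries.

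The comparison, the test, its alternatives, the 37 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis factors, RNA polymerases I and III, translation factors, classes of non-coding RNA, mitochondrially encoded and Ty genes, cohesin, condensin, histones, cell cycle clusters, stress and heat shock genes, metabolic regulons, the proteasome, cell wall and DNA damage genes, telomeric families, mating, pheromone and meiosis genes, and strain markers. Lists with at least 3 measured members were tested with camera from limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists. Camera compares a list's genes with all other genes. Members were counted as higher or lower after adjustment over all features, and again with the p-values adjusted over the list alone. Estimating the correlation between the genes of each list, and the fry test of whether a list's genes move one way, were alternatives. Features within 25 kb of a centromere, within 20 kb of a chromosome end, and convergent with their downstream neighbour were tested in the same way. Named genes are the 10 with the largest rise and the 10 with the largest fall among those past the threshold, with a mean RPKM of at least 5 and no overlap between the groups; the 3 members with the smallest p in the direction of each list that passed; and all measured cohesin and strain marker genes. Genes named outside this rule are said to be so. One gene that the rule names is not reported here. Further alternatives were other scalings, pseudocounts and filters, moderation without a trend, narrower and wider distance limits, the replicate number as a block, and leaving out each library. Added after seeing the data were fits without features of chromosome IX, without chromosomes I and IX, without features that overlap another, and with voom (limma) on the recovered reads, and the medians per chromosome over coding genes of the reference with a mean RPKM of at least 5. The replicate numbers are not stated to pair cultures, and no block was used in the reported fit.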

Results

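Transcript levels were compared between WT yeast and the cohesin loader mutant scc2-4, with 3 biological replicates per genotype according to the series' design. Each library held between 14730000 and 21930000 reads assigned to features. All pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 23.5 to 127, so no pair was taken as 1 library sequenced again. This does not show that the libraries came from separate cultures, which rests on the series' design. WT replicate 1 stood apart from the other WT libraries. Its correlation with them across features was 0.977 and 0.968 on the log2 scale, against 0.993 between WT replicates 2 and 3 and 0.990 to 0.993 among the mutant libraries. The first principal component held 78.3% of the variance and placed WT replicate 1 at -42.9, the other WT libraries at -16.6 and -11.7, and the mutant libraries between 19.2 and 29.4. The preparation of the WT libraries is assumed to be ribo-depletion, as for the mutant, because their column names do not give it.

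The comparison of scc2-4 with WT asks which transcript levels differ between the mutant and WT cultures. It does not separate an effect of the cohesin loader from differences in growth state or chromosome copies between the cultures. As lists tested in camera, ribosome biogenesis factors and genes of RNA polymerase I were higher in the mutant, and stress-induced, heat shock and respiratory genes were lower. None of these calls held with an estimated correlation (adjusted p = 0.705 for respiration and adjusted p = 0.702 for the others, with an estimated correlation). HXT4, a high-affinity glucose transporter gene, fell 13.5-fold, from 687 ± 327 to 47.6 ± 14.0 RPKM (mean ± SD, n = 3 per genotype). ADE17, an enzyme gene of purine synthesis, fell 9.32-fold, from 634 ± 238 to 63.9 ± 2.86 RPKM. AIR1, which encodes an RNA-binding subunit of the TRAMP nuclear surveillance complex, rose 7.27-fold, from 7.48 ± 3.79 to 55.5 ± 4.44 RPKM. Genes on chromosome IX were higher as a group in camera, with a median change of 1.81-fold (adjusted p = 0.548 with an estimated correlation).

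Of 6559 features tested, 2133 passed an adjusted p of 0.05 in limma, 1149 of them higher and 984 lower in scc2-4, and 537 of these changed at least 2-fold on the log2(RPKM + 1) scale. The values of the 2 genotypes did not overlap for 56.1% of features, where chance gives 10% for a single feature. Features vary together, so this share does not test the genotype difference against chance. On chromosome IX 174 of 244 features were higher and 5 lower, and on the other chromosomes 975 of 6315 were higher and 979 lower. The count changed when 1 library was left out, which also lowers the power. It was 1415 without WT replicate 2 and 1039, 781 and 766 without scc2-4 replicates 1, 2 and 3. Of these last 3 sets, 1010, 776 and 761 features were also called with all 6 libraries. Without WT replicates 1 and 3 the count was 2442 and 2335.

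Among the 10 largest rises, 4 lay on chromosome IX: AIR1 (YIL079C, sacCer3 chromosome IX, 210923 to 212005, minus strand), UTP25 (5.38-fold), SHQ1 (4.49-fold) and YIL096C (4.37-fold). UTP25 encodes a component of the small-subunit processome and SHQ1 an assembly factor of H/ACA ribonucleoproteins. YGR079W rose 5.86-fold to 27.3 ± 2.21 RPKM. RRN11, a subunit gene of the RNA polymerase I core factor, rose 5.46-fold, from 2.72 ± 1.42 to 18.1 ± 0.792 RPKM. The remaining rises came from overlapping pairs whose reads cannot be separated: YBR056C-B (4.61-fold) with YBR056W-A (4.27-fold), and SLM6 (4.39-fold) with REI1 (4.23-fold), a ribosome biogenesis gene. Without a scc2-4 replicate REI1 had an adjusted p of 0.0609 to 0.0683, and SLM6 had 0.0520 and 0.0548 without scc2-4 replicates 2 and 3. Their adjusted p was 0.0188 and 0.0136 with all 6 libraries, and 0.000436 and 0.000179 at the lowest over the alternatives.

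The largest falls after HXT4 (YHR092C, chromosome VIII, 287081 to 288811, minus strand) were YNR034W-A, 12.1-fold, and RGI1, a gene of respiratory growth, 9.56-fold with the overlapping YER067C-A. The WT libraries varied widely for both, at 818 ± 601 RPKM for YNR034W-A and 1614 ± 898 RPKM for RGI1. The transporter genes HXT6 and HXT7 fell 9.48-fold and 8.91-fold, from 42.1 ± 31.1 and 113 ± 74.7 RPKM in WT. They are near-identical copies, and their single values are uncertain. ADE17 (YMR120C, chromosome XIII, 507502 to 509280, minus strand) had the smallest adjusted p of these genes, 0.00129. YPR160W-A fell 8.90-fold, from 439 ± 317 RPKM in WT, and lies within GPH1, the glycogen phosphorylase gene. PGM2, a phosphoglucomutase gene, fell 8.69-fold from 732 ± 451 to 76.3 ± 26.1 RPKM, and GSY1, a glycogen synthase gene, fell 8.62-fold from 570 ± 211 to 65.4 ± 24.9 RPKM.

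**Figure D1:**
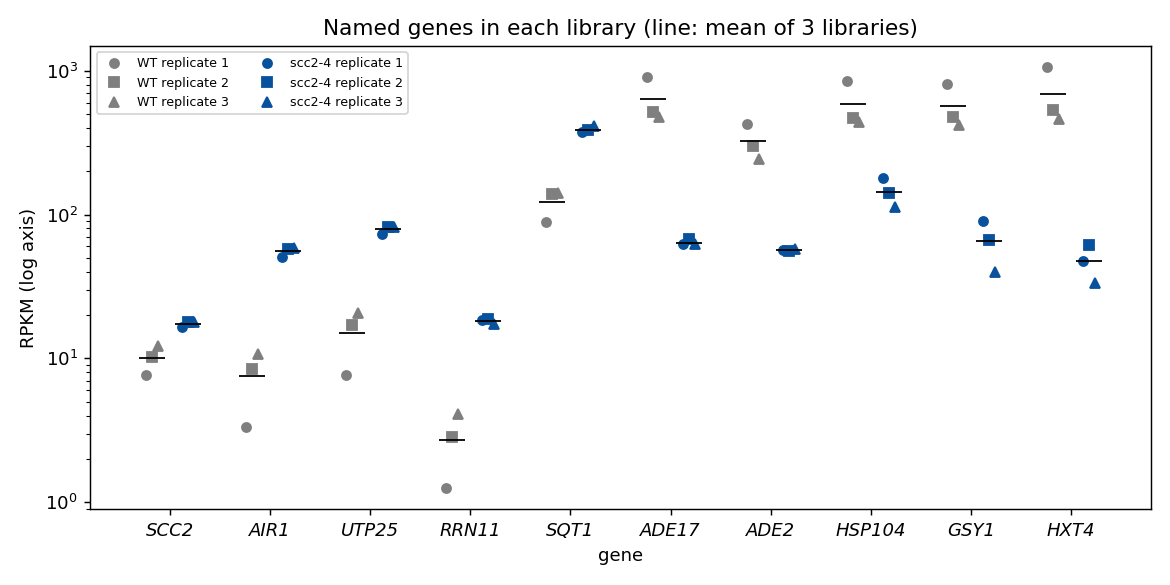
RPKM of 10 named genes (log axis) in each library, WT in grey and scc2-4 in blue, with a symbol per replicate and a line at the mean of 3 libraries. The mutant libraries lie close together for genes such as ADE17, at a mean of 63.9 RPKM, and spread more for GSY1 and HXT4, and WT replicate 1 lies farthest from the mutant for all 10 genes drawn.

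SCC2 itself (YDR180W, chromosome IV, 821295 to 825776, plus strand) was 1.71-fold higher in the mutant, 17.4 ± 0.812 against 10.03 ± 2.24 RPKM (adjusted p = 0.0214, limma). SCC4, its partner in the loader, was 1.27-fold higher, 17.1 ± 0.641 against 13.4 ± 0.291 RPKM (adjusted p = 0.0279, limma). The allele encodes a mutant protein, so these levels do not check the genotype labels. Of the 13 measured genes of cohesin, its loader and its regulators, 7 rose, 1 fell and 5 did not pass, and the counts adjusted over the list alone were also 7 and 1. The cohesin subunit genes MCD1 (2.16-fold), IRR1 (2.17-fold, on chromosome IX), SMC3 (1.68-fold) and SMC1 (1.37-fold) rose, as did PDS5 (1.41-fold). PDS1, the securin gene, fell 1.54-fold from 18.7 ± 1.58 to 11.8 ± 2.03 RPKM. RAD61, ECO1, ESP1, SGO1 and HOS1 had log2 changes of -0.11, 0.029, -0.022, -0.0068 and 0.18 and did not pass. RAD61 was at -0.039 without WT replicate 1 and HOS1 at 0.087 without WT replicate 3. As a list these genes did not pass against all other genes (camera, adjusted p = 0.0667; adjusted p = 0.702 with an estimated correlation), although adjusted p was 0.0464 without WT replicate 3 and 0.0449 without scc2-4 replicate 3, and it ranged from 0.0449 to 0.702 over the alternatives run with camera. The call on SCC2 ended without any scc2-4 replicate (adjusted p = 0.0554, 0.0773 and 0.0797), those on SCC4 and SMC1 without WT replicate 2 or any scc2-4 replicate (0.0573 to 0.0973 and 0.0553 to 0.0729), and that on PDS5 without any scc2-4 replicate (0.0705 to 0.107). The lowest adjusted p over the alternatives was 0.00659 for SCC2, 0.0219 for SCC4, 0.0127 for SMC1 and 0.0188 for PDS5.

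Ribosome biogenesis factors rose as a group in scc2-4: 83 of 144 were higher, 1 was lower and 60 did not pass, with 126 higher and 1 lower when adjusted over the list alone. Their median log2 change was 0.88 (camera, adjusted p = 2.0e-16; adjusted p = 0.702 with an estimated correlation). The smallest p-values belonged to SQT1 (3.25-fold, chromosome IX), YGR251W (2.33-fold) and SSF2 (2.27-fold, 10.8 ± 2.00 to 25.3 ± 0.786 RPKM). The member that fell, NOG2, overlaps SNR191 and was named after its value was seen. The list's median relative to the WT mean was -0.63, 0.24 and 0.39 in WT replicates 1 to 3 and 0.85, 0.89 and 0.96 in the mutant libraries, and without WT replicate 1 the change was 0.56. None of the 17 lists that passed in camera, 10 higher and 7 lower, passed with an estimated correlation, where 1 had an unadjusted p under 0.05. In fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, 13 lists passed. Of the 17 lists, 9 did not pass in fry, among them ribosome biogenesis factors (adjusted p = 0.0950), stress-induced genes (0.102), respiration (0.126), and mitochondrial (0.169) and cytosolic ribosomal proteins (0.321). The 5 that passed in fry and not in camera were ribosomal RNAs, cohesin, condensin, mating and meiosis genes. Of 15 genes of RNA polymerase I and its factors, 8 rose and 7 did not pass (9 adjusted over the list alone; median log2 change 0.94). RRN7 rose 2.60-fold and RRN6 1.92-fold beside RRN11 (camera, adjusted p = 0.00190; adjusted p = 0.702 with an estimated correlation). Their median was -0.54 in WT replicate 1 and 0.14 and 0.35 in the other WT libraries, and without WT replicate 1 the change was 0.59. Of 22 genes of RNA polymerase III and its factors, 8 rose, 1 fell and 13 did not pass (10 and 1 adjusted over the list alone; median 0.47). RPC10 (1.82-fold), RPC17 (2.01-fold) and RPC19 (3.28-fold, overlapping YNL114C) had the smallest p-values among those that rose (camera, adjusted p = 0.0372; adjusted p = 0.702 with an estimated correlation). Its call ended without scc2-4 replicate 1 (adjusted p = 0.0729) and without features that overlap another (0.110), in a range of 0.0130 to 0.702 over the alternatives. The 1 that fell was MAF1, a repressor of RNA polymerase III, chosen after its value was seen. The calls on RPC17 and RPC19 ended without scc2-4 replicate 3 (adjusted p = 0.0527 and 0.0593), and that on RPC19 also without scc2-4 replicate 2 (0.0538), against 0.00113 and 0.000662 at the lowest over the alternatives. The median of this list was -0.30 in WT replicate 1, and without that library the change was 0.20.

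Of 138 cytosolic ribosomal protein genes, 15 rose, 1 fell and 122 did not pass, 8 and 0 when adjusted over the list alone. Their median log2 change was 0.30, with 127 above 0 (camera, adjusted p = 6.6e-05; adjusted p = 0.823 with an estimated correlation). RPL34B (2.27-fold), RPL2B (2.04-fold) and RPS24B (2.66-fold) had the smallest p-values, and all 3 lie on chromosome IX, which held 5 of the list's measured members, all of them higher. RPL15B, named after its value was seen, was the member that fell. Many of these genes have near-identical copies, and their single values are uncertain. Without WT replicate 1 the list no longer passed (median 0.14, adjusted p = 0.0517; range 1.0e-06 to 0.823 over the alternatives). The list's median was -0.33 in that library, 0.16 and 0.19 in the other WT libraries and 0.19, 0.22 and 0.52 in the mutant libraries. Of 39 translation initiation and elongation factor genes, 8 rose and 31 did not pass (7 adjusted over the list alone; median 0.38). SUI1 rose 2.13-fold to 516 ± 89.7 RPKM, EFB1 2.13-fold and HCR1 1.34-fold (camera, adjusted p = 0.000762; adjusted p = 0.797 with an estimated correlation). EFB1 lies on chromosome I and overlaps SNR18, and its call ended without scc2-4 replicate 1 or 3 (adjusted p = 0.0547 and 0.0563), as did that on HCR1 without scc2-4 replicate 2 or 3 (0.0793 and 0.0789); the lowest over the alternatives was 0.00523 for EFB1 and 0.00947 for HCR1. The factor list's median was -0.35 in WT replicate 1 and 0.13 and 0.20 in the other WT libraries, and without WT replicate 1 the change was 0.20.

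**Figure D2:**
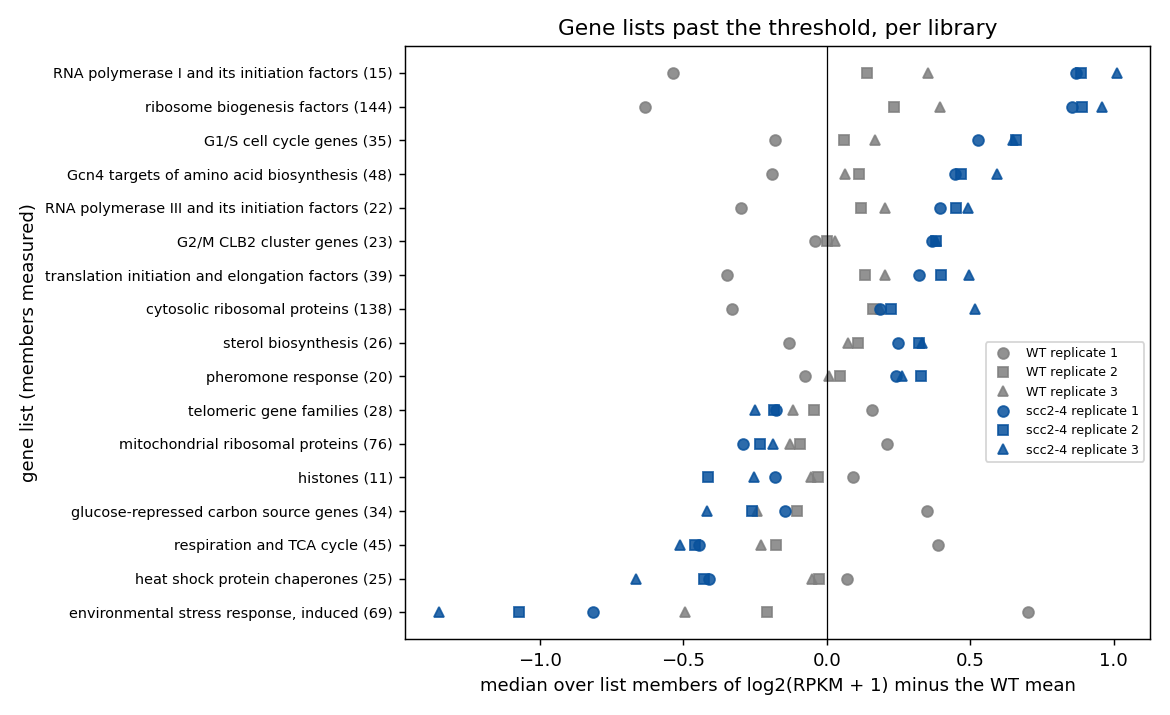
Median over the measured members of each of the 17 gene lists that passed, as log2(RPKM + 1) minus the mean of the WT libraries (horizontal axis), with WT libraries in grey and scc2-4 libraries in blue. WT replicate 1 lies on the far side of the other WT libraries from the mutant, at -0.63 for ribosome biogenesis factors and 0.70 for stress-induced genes.

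Genes induced in the environmental stress response fell: 36 of 69 were lower, 5 were higher and 28 did not pass, 41 lower and 5 higher when adjusted over the list alone. Their median log2 change was -1.08 (camera, adjusted p = 1.0e-09; adjusted p = 0.702 with an estimated correlation). HSP78, a mitochondrial chaperone gene, fell 3.95-fold from 110 ± 30.3 to 26.6 ± 4.95 RPKM, and GPD1, which encodes an enzyme of glycerol synthesis and overlaps YDL023C, fell 4.05-fold, beside GSY1. The 5 that rose, named after their values were seen, were SSA3, XBP1 (chromosome IX), SDS23, PHM7 and GRE1. The list's median was 0.70, -0.21 and -0.49 in WT replicates 1 to 3 and -0.81, -1.07 and -1.35 in the mutant libraries, and the change was -0.75 without WT replicate 1. Of 25 heat shock chaperone genes, 15 fell, 1 rose and 9 did not pass (16 and 1 adjusted over the list alone; median -0.53). HSP104, a disaggregase gene, fell 3.91-fold from 589 ± 229 to 144 ± 33.8 RPKM and HSP42 4.10-fold (camera, adjusted p = 9.6e-05; adjusted p = 0.702 with an estimated correlation). SSA3 was the member that rose, and several of these genes have close relatives. The list stood at 0.069 in WT replicate 1 and at -0.026 and -0.051 in the other WT libraries.

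Respiratory genes were lower too. Of 45 genes of respiration and the TCA cycle, 20 fell, 1 rose and 24 did not pass (24 and 1 adjusted over the list alone; median log2 change -0.45). NDI1, an NADH dehydrogenase gene, fell 3.20-fold, SDH1 3.23-fold from 117 ± 60.5 to 32.7 ± 5.42 RPKM, and QCR10 2.69-fold (camera, adjusted p = 3.6e-07; adjusted p = 0.705 with an estimated correlation). The member that rose, KGD1, lies on chromosome IX and was picked after its value was seen. Of 76 mitochondrial ribosomal protein genes, 19 fell, 1 rose and 56 did not pass, with the same counts adjusted over the list alone. MRPL25 fell 1.62-fold, MRPL1 1.59-fold and RSM19 1.49-fold (median -0.23; camera, adjusted p = 1.1e-05; adjusted p = 0.758 with an estimated correlation). Without WT replicate 1 the list's median was -0.13. RSM25, the member that rose, is on chromosome IX. The call on RSM19 ended without scc2-4 replicate 2 or 3 (adjusted p = 0.0571 and 0.0565; 0.00440 at the lowest over the alternatives). Of 34 glucose-repressed carbon source genes, 9 fell, 2 rose and 23 did not pass, the same counts adjusted over the list alone (median -0.34; camera, adjusted p = 0.00901; adjusted p = 0.818 with an estimated correlation). HXT2 fell 2.68-fold from 1490 ± 328 to 551 ± 110 RPKM and MAL11, which overlaps YGR290W, 3.52-fold. YAT1, on chromosome I, and ADH2 rose, both picked after their values were seen. This list no longer passed without WT replicate 1 (median -0.18, adjusted p = 0.0904; range 0.00204 to 0.818 over the alternatives). Medians of the respiratory, mitochondrial ribosomal and glucose-repressed lists in WT replicate 1 were 0.39, 0.21 and 0.35 above the WT mean.

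Cell cycle genes of the G1/S cluster rose: 23 of 35 were higher, none was lower and 12 did not pass (29 adjusted over the list alone; median log2 change 0.61). PCL1, a G1 cyclin gene, rose 2.31-fold from 14.5 ± 1.86 to 34.5 ± 3.31 RPKM, SVS1 1.72-fold, and PRI1, a DNA primase gene on chromosome IX, 1.86-fold (camera, adjusted p = 1.7e-07; adjusted p = 0.702 with an estimated correlation). In the G2/M cluster of CLB2, 13 of 23 genes rose, 1 fell and 9 did not pass (15 and 1 adjusted over the list alone; median 0.39). The mitotic cyclin genes CLB2 and CLB1 rose 1.84-fold and 1.85-fold, and MOB1, on chromosome IX, 1.82-fold (camera, adjusted p = 0.000393; adjusted p = 0.702 with an estimated correlation). In WT replicate 1 the G1/S list stood at -0.18 and the G2/M list at -0.042 relative to the WT mean. The member that fell was DBF2, chosen after its value was seen. Of 11 histone genes 3 fell and 8 did not pass (4 adjusted over the list alone; median -0.27). HTA1 fell 1.61-fold from 1150 ± 92.5 to 710 ± 54.2 RPKM, HTB1 1.55-fold and HHT2 1.34-fold (camera, adjusted p = 0.00437; adjusted p = 0.702 with an estimated correlation). The histone list stood at 0.093 in WT replicate 1. Histone genes have similar copies, and the call on HHT2 ended without WT replicate 2 or any scc2-4 replicate (adjusted p = 0.0689 to 0.129; 0.0223 at the lowest over the alternatives). Neither M/G1 genes (3 higher, 3 lower of 23; adjusted p = 0.892) nor condensin and Smc5/6 genes (5 higher, 0 lower of 13; adjusted p = 0.131) passed in camera. Adjusted over the list alone, the counts were again 3 and 3, and 5 and 0. The M/G1 genes CLN3, SWI4 and CDC6 rose and TEC1, PIR1 and SIC1 fell, and YCG1, NSE1, SMC4, YCS4 and SMC5 rose, all named after their values were seen.

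Amino acid biosynthesis genes controlled by Gcn4 moved both ways, with 22 of 48 higher, 5 lower and 21 not past the threshold (28 and 6 adjusted over the list alone; median log2 change 0.52; camera, adjusted p = 6.6e-05; adjusted p = 0.702 with an estimated correlation). ARG4 rose 2.28-fold from 74.0 ± 5.04 to 169 ± 15.9 RPKM, and LYS1, on chromosome IX, 3.11-fold. The 5 that fell, named after their values were seen, were GLN1, GDH1, HIS4, SER1 and SER3; GLN1 encodes glutamine synthetase and GDH1 a glutamate dehydrogenase. SER3 overlaps SRG1. Relative to the WT mean, the Gcn4 list stood at -0.19 in WT replicate 1 and the sterol list at -0.13. Of 26 sterol biosynthesis genes 4 rose and 22 did not pass (3 adjusted over the list alone; median 0.28; camera, adjusted p = 0.0313; adjusted p = 0.754 with an estimated correlation). CYB5 rose 2.101-fold, MVD1 1.57-fold and UPC2, a regulator of sterol genes, 1.32-fold. The other was ERG25, named after its value was seen. The list did not pass without WT replicate 1 (median 0.20, adjusted p = 0.0541; range 0.0125 to 0.754 over the alternatives). Calls on single members ended for CYB5 without scc2-4 replicate 2 or 3 (adjusted p = 0.0520 and 0.0634), for MVD1 without any scc2-4 replicate (0.0677 to 0.0692) and for UPC2 without WT replicate 3 or any scc2-4 replicate (0.0507 to 0.0988). The lowest over the alternatives was 0.00176, 0.00286 and 0.0216 for these genes in turn.

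Of 20 pheromone response genes 7 rose, 1 fell and 12 did not pass (9 and 2 adjusted over the list alone; median log2 change 0.27; camera, adjusted p = 0.0471; adjusted p = 0.702 with an estimated correlation). FIG1 rose 3.17-fold, from 0.873 ± 0.168 to 5.02 ± 1.55 RPKM, PRM3 2.06-fold and PRM10, which overlaps YJL107C, 1.54-fold. STE18, which overlaps YJR087W, was the member that fell, named after its value was seen. The list's call ended without WT replicate 1 (adjusted p = 0.105), scc2-4 replicate 1 (0.0562) or scc2-4 replicate 2 (0.0681), and also without centring (0.0574) and with a mean RPKM of at least 5 (0.173), in a range of 0.0242 to 0.702 over the alternatives run with camera. Of 28 genes of telomeric families 6 fell, 2 rose and 20 did not pass, the same adjusted over the list alone (median -0.21; camera, adjusted p = 0.0316; adjusted p = 0.702 with an estimated correlation). COS8 fell 6.56-fold from 35.3 ± 14.2 to 4.23 ± 0.297 RPKM, COS12 4.34-fold and PAU3 2.78-fold, all members of repeated families whose values are uncertain. The pheromone list stood at -0.075 and the telomeric list at 0.16 in WT replicate 1. AAD16 and AAD6 rose, both picked after their values were seen. This list did not pass without WT replicate 1 (adjusted p = 0.0797), with no filter (0.208), with a mean RPKM of at least 5 (0.0954) or without chromosomes I and IX (0.0752), in a range of 0.0134 to 0.702.

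Lists of non-coding RNA did not pass in camera. Of 76 small nucleolar RNAs 9 were higher and 8 lower (9 and 6 adjusted over the list alone; median log2 change -0.19, adjusted p = 0.243). That median was -0.048 without WT replicate 2 and -0.082 without scc2-4 replicate 2 (adjusted p = 0.880 and 0.683; range 0.0622 to 0.957 over the alternatives run with camera). None of 6 spliceosomal RNAs passed, and none did at an unadjusted p of 0.05 in limma (list adjusted p = 0.447). Of 109 transfer RNA genes 8 were higher and 5 lower (3 and 2 adjusted over the list alone; adjusted p = 0.707), of 4 other structural RNAs 0 changed in limma, 1 at an unadjusted p of 0.05 (adjusted p = 0.978), and of 5 ribosomal RNA features 2 fell (2 adjusted over the list alone; adjusted p = 0.143). The 2 were RDN58-1, 154 ± 2.16 in WT and 106 ± 7.67 RPKM in scc2-4, and RDN37-1, 5.26 ± 0.224 and 3.75 ± 0.0945 RPKM, both picked after their values were seen. RDN58-1 overlaps YLR154W-E and lies within RDN37-1, the feature of the ribosomal RNA precursor. Reads of RDN58-1 may therefore be counted in both, and the 2 falls need not be independent. The 5 transfer RNAs that were lower, also picked so, were tS(UGA)Q2, tG(GCC)G1, tD(GUC)O, tN(GUU)P and tG(GCC)P2. Of 14 ribosomal DNA features 9 were at 0 in all libraries, so these values need not follow ribosomal RNA content. The ribosomal RNA list was also set to include the mitochondrial ribosomal RNAs. Small nucleolar RNAs took 8.62% of reads in features in WT and 7.28% in the mutant, and protein-coding genes 78.0% and 80.4%. Features of the class of other non-coding RNA fell about as much, from 8.71% to 7.42%. Each of these differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted p = 0.175 over 7 classes).

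The other lists did not pass in camera either. Higher and lower counts were 1 and 0 of 23 mitochondrially encoded genes (adjusted p = 0.699), 0 and 1 of 23 Ty genes (0.754), 6 and 3 of 28 sulfur and methionine genes (0.913), 1 and 4 of 19 glycolysis genes (0.176), 1 and 0 of 15 phosphate genes (0.295) and 7 and 4 of 25 iron genes (0.901). They were 2 and 1 of 36 proteasome genes (0.754), 5 and 4 of 25 cell wall genes (0.606), 4 and 3 of 15 DNA damage genes (0.754), 10 and 3 of 39 meiosis genes (0.288) and 5 and 0 of 11 mating-type-specific genes (0.340). Adjusted over the list alone the counts were 0 and 0 for mitochondrially encoded and for Ty genes, 1 and 0 for the proteasome, 5 and 3 for DNA damage and 5 and 2 for mating genes, and were the same for the other lists of this paragraph. Among glycolysis genes TDH1, ENO1, HXT3 and HXK2 fell and CDC19 rose, all named after their values were seen, and that list passed without WT replicate 1 (adjusted p = 0.0492; range 0.0492 to 0.823 over the alternatives). ENO1 and TDH1 have near-identical copies, and CDC19, on chromosome I, overlaps YAL037C-B. Further members, named after their values were seen, were PHO86, the mitochondrial Q0297, RPN4, RPN2 (chromosome IX) and the DNA damage genes RNR3 (chromosome IX), HUG1, DIN7 and PLM2 among those that rose, and YGR109W-A, RPN11, TSA2, UBI4 and PHR1 among those that fell. Also higher were the mating genes MFA1, BAR1 (chromosome IX), STE2, MF(ALPHA)2 and STE3 and the cell wall genes CHS3, CRH1, KDX1, YLR194C and SCW10. Lower were the cell wall genes TIR1, TIR2, DAN1 and CWP2, the iron genes FIT1, ARN2, MRS4 and ENB1, the transport genes MUP3 and MMP1 with STR3, and the meiosis list's IME4, IME2 and YPR036W-A. Ty genes had a median of -0.00086 and a mean of 0.00062. Sulfur and methionine genes had a median of 0.15 and a mean of -0.014, with a median of 0.057 without WT replicate 3 and of 0.093 and 0.098 without scc2-4 replicates 1 and 3, and strain markers a median of 0.34 and a mean of -0.0068.

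Of genes that BY4741 lacks, LEU2 and MET17 were listed at 0 in all libraries, and URA3 at 0 in all but scc2-4 replicate 2, at 0.06 RPKM. Of 6 measured markers 3 rose, 1 fell and 2 did not pass (4 and 1 adjusted over the list alone; camera, adjusted p = 0.363). ADE2, a purine synthesis gene, fell 5.45-fold from 323 ± 93.4 to 56.6 ± 0.819 RPKM. LYS2 rose 1.73-fold, TRP1, which overlaps YDR008C, 1.28-fold and CAN1 1.25-fold. HIS3, which overlaps YOR203W, and HO had log2 changes of 0.20 and 0.73, and HIS3 was at 0.091 without scc2-4 replicate 3. HO passed without WT replicate 1 (log2 change 0.36, adjusted p = 0.00925) and without WT replicate 3 (0.93, adjusted p = 0.0489). The calls on LYS2, TRP1 and CAN1 ended without some libraries: LYS2 without scc2-4 replicate 2 or 3 (adjusted p = 0.0733 and 0.0725), and TRP1 and CAN1 without every library except WT replicate 1 (0.0708 to 0.110 and 0.0646 to 0.109) and also without centring (0.0609 and 0.0599). The lowest over the alternatives was 0.00562 for LYS2, 0.00497 for TRP1 and 0.00948 for CAN1, and the range for HO was 0.00925 to 0.203.

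Chromosome medians, computed after seeing the data, set chromosome IX apart. Over its 192 coding genes with a mean RPKM of at least 5, the median log2 change was 0.86 (quartiles 0.44 and 1.13), with 92.2% of genes above 0, 144 higher and 3 lower (camera over chromosomes, adjusted p = 7.9e-26; adjusted p = 0.548 with an estimated correlation). The median was 0.70, 0.92 and 0.94 in scc2-4 replicates 1, 2 and 3, and between -0.021 and 0.073 in the WT libraries, each against the other WT libraries. Chromosome I had a median of 0.64 over 73 genes in scc2-4 replicate 1, against 0.054 and -0.00036 in scc2-4 replicates 2 and 3. On the other nuclear chromosomes no mutant library had a median outside -0.098 to 0.11. Position within chromosomes was compared because cohesin is dense near centromeres and between convergent genes. Genes within 25 kb of a centromere (78 higher, 71 lower of 441; median 0.052), within 20 kb of a chromosome end (22 higher, 28 lower of 158; median -0.15) and convergent with their neighbour (546 higher, 464 lower of 2970; median 0.060) did not pass in camera (adjusted p = 0.878, 0.0974 and 0.878). The camera test of the centromere class pointed down although its median was above 0. The chromosome-end median was -0.091 without WT replicate 1 (adjusted p = 0.416) and -0.084 without scc2-4 replicate 3 (0.325), and the centromere median was 0.034 without scc2-4 replicate 3 (adjusted p = 0.885; range 0.440 to 0.956 over the alternatives). The chromosome-end class passed at a narrower distance limit (adjusted p = 0.00555) and without scc2-4 replicate 1 (0.0203), in a range of 0.00555 to 0.774 over the alternatives.

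**Figure D3:**
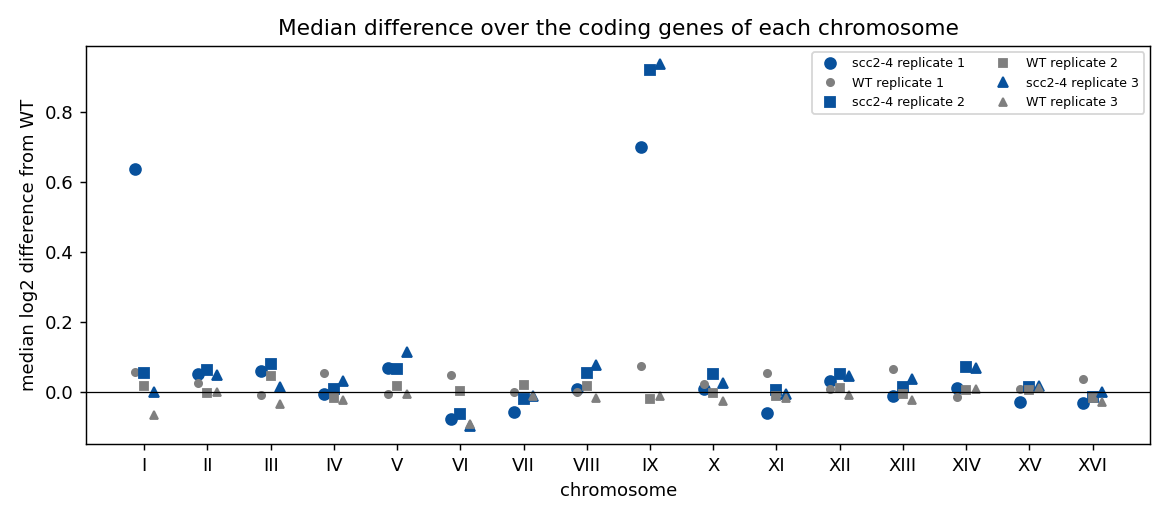
Median log2 difference over the coding genes of each nuclear chromosome, for each scc2-4 library against the mean of the 3 WT libraries (blue) and each WT library against the other WT libraries (grey). Chromosome IX lies at 0.70 to 0.94 in the mutant libraries, and chromosome I at 0.64 in scc2-4 replicate 1.

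**Figure D4:**
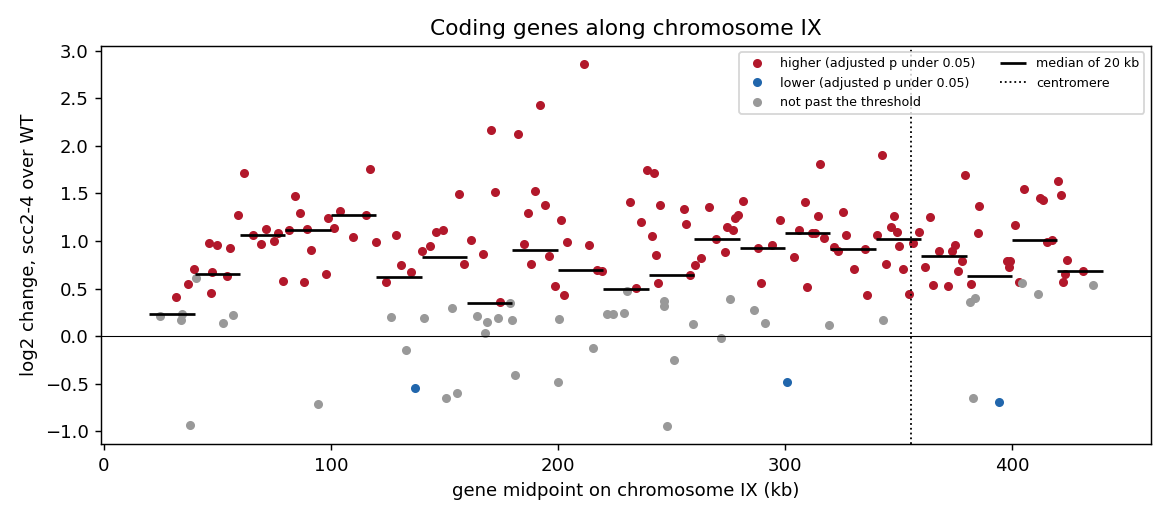
Log2 change of 192 coding genes against their midpoint on chromosome IX in kb, coloured by the call at an adjusted p of 0.05, with the median of each 20 kb as a black line and the centromere as a dotted line. All 21 of these medians are above 0, from 0.24 to 1.27.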

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

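The fits without chromosome IX or I, without overlapping features and with voom were chosen after seeing the data. Outside the fits that leave out a library, the number of changed features stayed between 1763 and 2341 against 2133, and no feature called in the main setting changed sign in any setting that tested it. The 1763 came from the fit without overlapping features, which tested only 5327 features. The main setting called 1723 of these. Leaving out 1 library gave 766 to 2442 changed features (373 to 1360 higher, 386 to 1123 lower); fewer libraries lower the power, and why the count rose without WT replicate 1 (2442) or WT replicate 3 (2335) was not tested. The number of lists past the threshold was 17, between 13 and 18 with 1 library left out, and 0 with an estimated correlation, in which genes of a list that vary together count for less. Position classes past the threshold numbered 0, and 1 at the narrower distance limits; without 1 library they were 0 to 1, and the cause was not tested. With the replicate block 2341 features were called (1270 higher, 1071 lower). Same-numbered libraries had correlations of deviations of 0.305, -0.062 and 0.353; WT replicates 1 and 3 correlated best with their own number and WT replicate 2 with scc2-4 replicate 3 (0.260). With 1 same-numbered pair below 0.1 and no pairing stated, the numbers were not taken to pair the cultures. The other same-numbered pairs had the highest correlations of all pairs, so a pairing or a shared batch stays open. The block ended the calls of the pheromone list (adjusted p = 0.0667) and TRP1 (0.0510). As deposited, 58.7% of calls were higher, against 53.9%. Voom called 2190 features and shared 2048 with the main test. Fits without chromosome IX, and without chromosomes I and IX, called 1922 and 1934, where the main setting called 1954 and 1930 of the features they tested. Of 79 named genes past the threshold, 18 lost the call when 1 library was left out and 61 kept it in every setting that tested them.

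Signs changed in 36 values, none past the threshold in either fit, and the cause was not tested. The Ty median became 0.0044 with a pseudocount of 5, 0.030 with no filter, 0.032 without chromosome IX, 0.036 without I and IX, and 0.0030 to 0.098 without 1 library. Other structural RNAs gave -0.0073 as deposited, -0.0038 with no filter, -0.072 without overlapping features, -0.0019 with voom and -0.041 to 0.074 without 1 library. At a mean RPKM of at least 5, transfer RNAs gave -0.042 and meiosis genes -0.22; at the narrower limit the centromere class gave -0.0047. SGO1 gave 0.014 without chromosome IX and 0.0098 without overlapping features. Without 1 library, ranges were -0.10 to 0.054 for SGO1, -0.052 to 0.022 for ESP1, -0.058 to 0.10 for ECO1, -0.063 to 0.044 for the proteasome, -0.0021 to 0.19 for mitochondrially encoded genes, -0.034 to 0.15 for M/G1, -0.20 to 0.037 for glycolysis and -0.067 to 0.14 for iron genes. The comparison with total RNA and the fit over 9 libraries were not run, because 3 libraries were not analysed here.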

Other observations

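Except for the count over other splits of the libraries, the tests in this part were chosen after the results they bear on had been seen. Of the genes of purine synthesis and its one-carbon supply, most were lower in scc2-4. Of 13 such genes, 12 fell, and only ADE16 did not pass (126 ± 10.2 in WT, 111 ± 3.92 RPKM in the mutant). Besides ADE17 and ADE2, SHM2 fell from 651 ± 212 to 176 ± 12.1 RPKM, ADE1, on chromosome I, from 437 ± 116 to 144 ± 34.3, ADE13 from 781 ± 150 to 279 ± 11.1 and MTD1 from 194 ± 41.5 to 73.4 ± 5.76 RPKM (mean ± SD, n = 3). The median log2 change was -1.03. The median was -1.003 when the mutant was compared with WT replicates 2 and 3 alone, and those libraries differed from WT replicate 1 by a median of -0.33. GUA1, which acts later in the path to GMP, rose 1.52-fold, while IMD2, IMD3 and IMD4 had log2 changes of -0.11, 0.45 and 0.40 and did not pass. As a list these genes had an unadjusted camera p of 4.4e-11, an unadjusted p of 0.0409 with an estimated correlation and an unadjusted fry p of 0.000137, which are not independent evidence because the genes were grouped after their values were seen.

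Small nucleolar RNAs were also counted by class, a grouping made after the data were seen. Of 46 box C/D RNAs, which guide methylation, 9 rose and 2 fell, with a median log2 change of 0.077 (quartiles -0.25 and 0.55). Of 29 H/ACA RNAs, which guide pseudouridylation, 0 rose and 6 fell, with a median of -0.30 (quartiles -0.48 and -0.16). Whether the change differs between the classes was not tested. The classes also differ in length, and the values differ with overlap too. The box C/D features are shorter, with a median span of 97.5 bases against 204. The 12 small nucleolar RNAs that overlap another feature had a median of 0.27, and the 64 that overlap none -0.21. Among DNA damage genes HUG1 rose 2.45-fold and RNR3, on chromosome IX, 3.35-fold, both picked after their values were seen. That list had 4 genes higher and 3 lower of 15 and did not pass (camera, adjusted p = 0.754).

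Genes of chromosome IX were higher in all 3 mutant libraries. An origin in whatever sets WT replicate 1 apart is argued against, since the chromosome's medians in the WT libraries, relative to the WT mean, spanned only 0.063. That span does not bear on a growth state particular to the mutant cultures, and growth was not measured. Reads of overlapping features are argued against by a median log2 change of 0.86 over its genes that overlap no other. An extra copy of chromosome IX in the mutant cultures is a candidate explanation: the median was 0.79 on the right arm and 0.89 on the left, and the medians of all 21 stretches of 20 kb were above 0. Whether a copy gain exists was not measured in DNA, and a regional effect of the scc2-4 allele itself stays open as untested.

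In scc2-4 replicate 1 alone, genes of chromosome I were higher. Whatever sets WT replicate 1 apart is argued against as the origin, since chromosome I medians spanned 0.081 over the WT libraries. A state particular to that mutant culture was not tested. An extra copy of chromosome I in all or part of that culture is a candidate explanation, with medians of 0.64 over 57 genes of the left arm and 0.63 over 16 of the right arm. In the other mutant libraries the arms had medians of -0.0067 to 0.10.

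In scc2-4, 36 of 69 stress-induced genes were lower and 5 higher, and 83 of 144 ribosome biogenesis genes were higher and 1 lower (adjusted p = 0.702 for each list with an estimated correlation). A growth-state difference between the cultures is a candidate explanation, because the median over all 213 genes of both lists, with the sign of stress genes turned, was 0.96 from WT replicate 1 to the other WT libraries and 0.59 from those to the mutant. Across 6209 features outside chromosomes I and IX, which are not independent, the change from WT replicate 1 to 2 correlated with the change from WT replicate 3 to the mutant at r = 0.439, and the change from WT replicate 1 to 3 with that from WT replicate 2 to the mutant at r = 0.549; for WT replicate 2 to 3 and WT replicate 1 to the mutant, r was 0.259. Whether WT values from total RNA libraries could contribute cannot be told apart from genotype. The counted 5.8S ribosomal RNA feature was 1.45 times higher in WT. Ribosomal RNA features together took 1.92% of reads in features in WT and 1.96% in scc2-4. That class of 16 features also holds the mitochondrial ribosomal RNAs, and their part of the share was not separated. The share therefore does not show how much nuclear ribosomal RNA was counted. However, 9 of 14 ribosomal DNA features were at 0 in all libraries, so counted reads need not follow ribosomal RNA content. An effect of the scc2-4 allele, with or without a change in growth, stays open as untested.

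The 6 libraries can be split into 3 and 3 in 10 ways, so no share under 0.05 can be reached. In limma 1 split, the real one, gave 2133 changed features, and the highest of the other splits gave 0, with up to 125 features at an unadjusted p under 0.05.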
